A study of Glycyrrhiza uralensis with 24 samples.

How the data were processed

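Total RNA from stems and leaves and from roots of Glycyrrhiza uralensis was sequenced, with 3 libraries for each organ at 0 h (control) and after 2, 6 and 12 h in 150 mM NaCl. The deposited files hold 1 table per library, whose values are TPM per the file headers, the unit the authors deposited. The submitters' processing notes name fastp, HISAT2, StringTie, RSEM, DESeq2 and edgeR, and the versions, genome and annotation are not given in the sources used here. The salt protocol in the labels speaks both of drought and of NaCl, and the NaCl concentration and times were taken as labelled. Each file has 38135 rows for 34445 IDs, and 2751 IDs have several rows, up to 8 for one ID. Rows of 1 ID were summed, and no pair of libraries had identical files. Of the IDs, 5642 were at 0 in every library. The TPM of the listed genes summed to 431934 to 496981 per aerial library and 391447 to 510545 per root library. That is 43.2% to 49.7% and 39.1% to 51% of the full TPM scale, so the files list part of what the TPM were scaled over. Read counts were not used here, so depth is unknown and no counting interval is given.

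The comparisons, thresholds and alternatives were chosen before the data were examined, on the assumption that the files would hold counts. Since the values are TPM, log2(TPM + 1) was tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on genes with a mean of at least 0.5 TPM over the libraries of the fit. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. On this scale the pseudocount of 1 shrinks the fold changes of genes with low TPM. Each organ's 12 libraries were fitted together for its time comparisons (15744 genes in aerial parts, 16138 in roots). The 24 libraries were fitted together for the organ comparisons and for the difference of salt responses between organs, taken as roots minus aerial parts (16718 genes). The comparisons of 12 h with 2 h were added after the data were seen.

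The salt libraries carry numbers in their titles that aerial parts and roots share, while control titles follow another pattern, and an aerial and a root control share no number. For each of the 9 numbers, the residuals of the aerial and root library correlated over 16718 genes at 0.20 to 0.57, and each library's best partner was that of its own number. Aerial and root controls taken in the order of their titles correlated at 0.23 to 0.32, each with its own partner best, and other control pairs at -0.21 to -0.02. The labels do not state this order as a pairing. The numbers were therefore tried as a block, with a within-pair correlation of 0.33 in limma's duplicateCorrelation, and as a fixed block over the salt libraries. A block that also pairs the controls by order, with a within-pair correlation of 0.28, was added after the data were seen.

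No ID could be given a name from the files, so the rule for examples fell to its last clause: per comparison with controls, the 2 IDs that rose most and the 2 that fell most. They had to be called, with a mean of at least 10 in one group and every library of one group above every library of the other. The level of 10 was planned in CPM and was applied as 10 TPM. For the difference between organs the rule took called IDs of each sign with the lowest p and the same level, and a smaller number of these, chosen after their values were seen, is given. Fixed gene lists could not be matched to IDs and were not tested. An ID at 0 in every library of a group is given as listed at 0, with no fold change.

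Genes called in both organs or at several times were compared with independent lists by Fisher's exact test or by expectation, and with simulated data added after the data were seen. For the times, 100 data sets kept the shared controls by drawing the sign of the residuals for each library, with no salt effect or with the called changes of 6 h and 12 h moved to other genes of like level. For the organs, 100 data sets kept the pairs, controls by order, by drawing the sign for each pair, with no salt effect or with the called changes of roots moved in this way. Values per library were compared between controls and salt by exact permutation in Python 3.11.15 with scipy 1.17.1. The position of a library between controls and salt was computed with that library left out of the scale, from genes whose 2 h and 12 h libraries all lay more than 0.5 on the log2 scale above, or all below, every control. The pipeline was tested on simulated data with 200 changed genes, each with a mean of at least 5 TPM. Residuals were shuffled over libraries for each gene alone, which removed the correlation between genes and any outlying library. In these data 3.57% to 10% of calls were false over the comparisons. Alternatives were the pseudocount (0.1 and 5), the filter (none, or a mean of at least 1 TPM), 2 scalings, the libraries in the fit, a 2-fold minimum, blocks and each library left out in turn. Added after the data were seen were library quality weights, a test without a mean-variance trend, rows of one ID kept apart, the omission of both 6 h replicate 2 libraries, and organ-enriched sets from controls alone. For the share of listed TPM these sets were drawn anew for each split of the organ's libraries, with the controls of the other organ held, since a set drawn from the real controls would favour them.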

Results

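RNA-seq was carried out on Glycyrrhiza uralensis, a licorice legume whose roots hold glycyrrhizin and flavonoids such as liquiritin. Seedlings, 60 days old per the labels, were placed in 150 mM NaCl for 2, 6 or 12 h, and plants at 0 h served as controls. No control was taken at the later times, so time of day cannot be told apart from time in salt. This holds for comparisons with controls and between salt times. The labels give distilled water for the controls and NaCl in a nutrient solution (MS) for the salt groups, so each comparison of salt with control is also one of media. Aerial parts (stems and leaves) and roots were sampled, which gave 8 groups of 3 libraries, 24 in all. The study looked for genes and pathways behind the accumulation of pharmacologically active compounds in salt. The files list 34445 gene IDs in TPM, a length-scaled share of the transcripts in a library, and do not pair the IDs with gene names, so pathways were not analysed here and only a few IDs are given as examples. Sequencing depth cannot be read from TPM and is unknown. The labels do not say whether each library came from a separate plant, so the p-values measure the spread between these samples.

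The genes listed held a larger part of each library in controls than in salt in both organs. Their TPM summed to 485995 ± 10396 (SD, n = 3) in aerial controls and 446872 ± 12511 (n = 9) in aerial salt libraries, and to 495222 ± 19674 and 412991 ± 11869 in roots. Fewer IDs were above 0 in controls, with 17276 ± 163 against 18359 ± 285 in aerial parts and 17030 ± 212 against 18645 ± 341 in roots. Each of these 4 differences had a two-sided exact permutation p of 0.00909, the smallest that 220 splits of 12 libraries allow, and 0.017 after adjustment over 15 tests. IDs at 1 TPM or more did not differ in this test, with 12821 ± 343 against 12585 ± 468 in aerial parts (exact permutation p = 0.436, adjusted 0.545) and 12700 ± 188 against 12951 ± 230 in roots (exact permutation p = 0.127, adjusted 0.191). The control libraries carry another title pattern than the salt libraries, and no title pattern holds both, so a batch and the salt treatment cannot be told apart in any comparison with controls.

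**Figure D1:**
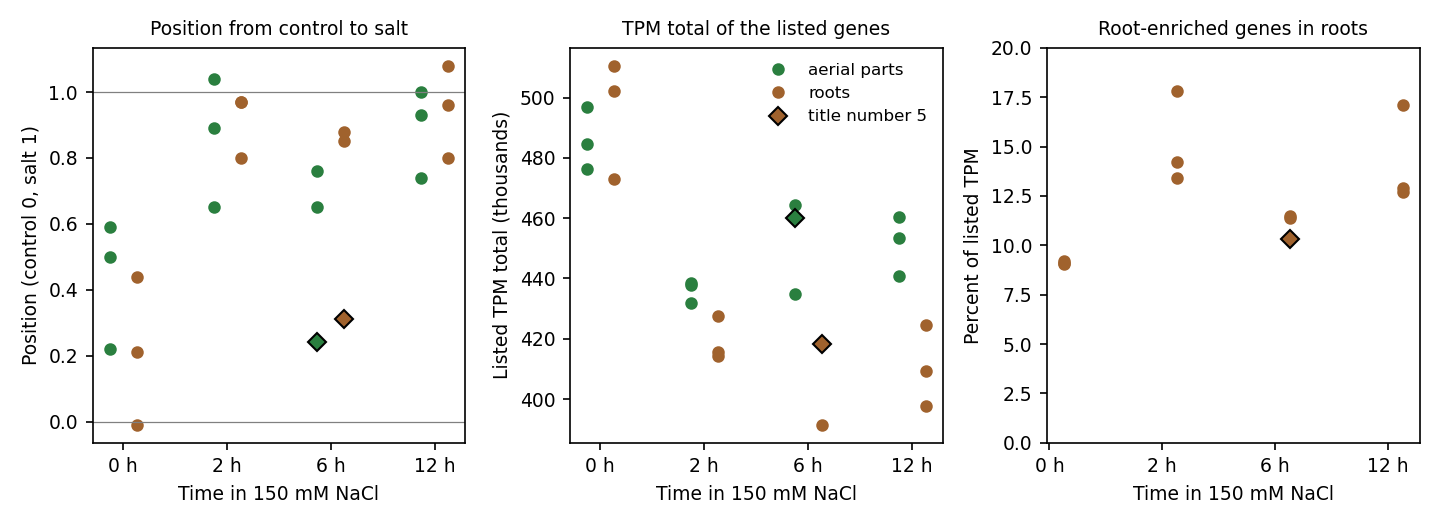
Each point is 1 library, by hours in 150 mM NaCl, for aerial parts and roots: its position between controls (0) and salt libraries (1), the summed TPM of the listed genes, and the percent of listed TPM in root-enriched genes (set from all libraries) in roots. The diamonds are 6 h replicate 2, at 0.24 in aerial parts and 0.31 in roots on the first scale, where the other salt libraries lie between 0.65 and 1.08.

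In aerial parts, 1060 of 15744 genes tested changed between controls and 2 h of salt, of which 427 rose and 633 fell. Glyur000049s00003133 rose from 5.88 ± 3.09 TPM (SD, n = 3) in controls to 814 ± 555 at 2 h (log2 fold change 6.72, SE 0.61, limma adjusted p = 0.000193) and stood at 37.5 ± 18.1 at 6 h and 8.13 ± 3.90 at 12 h. Glyur000063s00005870 was listed at 0 in 2 of the 3 controls and at 6.82 TPM in the other, and rose to 358 ± 236.5 at 2 h (7.17, SE 0.93, limma adjusted p = 0.00163). Glyur000027s00001583 fell from 580.3 ± 222 TPM to 1.29 ± 0.259 (-7.93, SE 0.32, limma adjusted p = 1.01e-06) and stood at 585 ± 190.5 at 6 h. Glyur000380s00017141 fell from 1907 ± 884 TPM to 4.97 ± 3.15 at 2 h (-8.38, SE 0.44, limma adjusted p = 6.6e-06), stood at 2163 ± 636 at 6 h, and was above the controls at 12 h, at 10799 ± 1867 (2.58, SE 0.44, limma adjusted p = 0.0176). For each ID given as an example of a change, all 3 libraries of one group lay above all 3 of the other. The median log2 fold change was 1.76 among genes that rose and -1.45 among those that fell. Over all genes tested the median was -0.16, and it was 0.01 with median-of-ratios scaling and -0.04 with each library scaled to its listed total. The share of higher genes among those called was 40.3%, against 60.3% and 54.2% under these scalings, so which direction held the larger number depended on the scaling. Without 2 h replicate 2 the count was 461, and without control replicate 1 it was 610.

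At 6 h no aerial gene passed limma's adjusted threshold, and the lowest adjusted p was 0.0871. At an unadjusted p under 0.05 there were 1804 genes, where 787 would be expected by chance. The count was 0 with library quality weights, 4 with a pseudocount of 0.1, 2 without a filter on low values and 25 with all 24 libraries in the fit. Left out in turn, 6 h replicates 1, 2 and 3 gave 2, 33 and 3 genes, and control replicates 1, 2 and 3 gave 3, 1 and 8. In simulated data of the same size, 65.2% of genes changed by 2 on the log2 scale were recovered in this comparison, and 7.35% of those changed by 1. The changed genes had a mean of at least 5 TPM, and residuals were shuffled over the organ's libraries gene by gene. An outlying library was thus not kept within its group, so recovery with such a library in the 6 h group was not measured. The 6 h replicate 2 library lay near the controls, at 0.24 on a scale where controls average 0 and salt libraries 1, while the controls, each left out of the scale in turn, lay between 0.22 and 0.59 and the other aerial salt libraries between 0.65 and 1.04.

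At 12 h, 434 aerial genes were called, 189 higher and 245 lower than in controls. Glyur000253s00020238 rose from 3.29 ± 3.51 TPM (SD, n = 3) to 159.8 ± 74.6 (log2 fold change 5.44, SE 0.57, limma adjusted p = 0.00211) and stood at 2.50 ± 1.57 at 2 h. Glyur000249s00015884 was listed at 0 in all 3 controls and at 42.14, 80.15 and 139.21 TPM in the 12 h libraries (limma adjusted p = 0.0138), and at 39.25 to 172.65 TPM at 2 h (limma adjusted p = 0.00561). Its 12 h call was lost without 12 h replicate 2 (limma adjusted p = 0.071) and without 12 h replicate 3 (limma adjusted p = 0.0706). Glyur001877s00044595 fell from 107.7 ± 48.3 TPM to between 0 and 0.73 (-6.27, SE 0.61, limma adjusted p = 0.00161), and Glyur000034s00002929 stood at 28.63 to 186.6 TPM in controls and was listed at 0 in all 3 libraries at 12 h (limma adjusted p = 0.0071). The median log2 fold change was 1.59 among genes that rose and -1.99 among those that fell. The share of higher genes was 43.5%, and 55.5% with scaling to the listed total. Left out in turn, 12 h replicates 1, 2 and 3 gave 141, 79 and 94 genes, and control replicates 1, 2 and 3 gave 153, 852 and 177.

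Between salt times, aerial expression changed further, with time of day not separated from time in salt. From 2 h to 6 h, 233 genes rose and 112 fell, and from 6 h to 12 h, 83 rose and 150 fell. From 2 h to 12 h, a comparison added after the data were seen, 816 genes rose with a median log2 fold change of 1.42 and 600 fell with a median of -1.87. The share of higher genes was 57.6% there, 54.3% with scaling to the listed total and 49.2% with median-of-ratios scaling, so the larger direction depended on the scaling. Among the genes called against controls at both 2 h and 12 h, 37 were higher at both times and 62 lower at both, where independent lists would share 5.13 and 9.85. A further 24 were higher at 2 h and lower at 12 h, and 13 were lower at 2 h and higher at 12 h, where independent lists would share 6.64 and 7.60. Counted anew over all genes with 1 library left out, opposite calls, 37 with all libraries, came to 22 without 2 h replicate 2, 13, 8 and 13 without 12 h replicates 1, 2 and 3, and 15 and 11 without control replicates 1 and 3. In the same order of libraries like calls, 99 with all libraries, came to 34, then 34, 21 and 22, then 43 and 55, and without control replicate 2 to 169. The genes counted need not be the same from one fit to the next. The fold changes at 2 h and 12 h share the same 3 controls, which cannot be split into parts of at least 2 libraries. In 100 simulated data sets with shared controls and the called changes of each time placed on genes drawn apart from those of the others, 14.9 genes were higher at both times (at most 96) and 20.5 lower at both (at most 80). The simulated 12 h lists were shorter than the real ones, on average 125 and 176 genes against 189 and 245. Relative to independent lists of the same lengths, the observed overlaps were 7.22 and 6.29 times as large. The simulated ones were 3.72 and 2.93 times as large on average and at most 9.47 and 5.79 times. The 37 genes higher at both times thus lay above the simulated mean but not beyond every simulated data set, as the 62 lower at both did. The opposite calls stood at 3.61 and 1.71 times, where the simulated ones came to at most 2.99 and 3.66 times. Of the opposite calls, only the 24 genes thus lay beyond the simulated ones. The covariance of the fold changes was 0.36, where simulated data with no salt effect gave 0.20 (at most 0.40). Genes are not independent replicates. The 2 h to 6 h count of 345 was 132 without 2 h replicate 2 and 164 without 6 h replicate 1. The 6 h to 12 h count of 233 was 154 and 150 without 6 h replicates 1 and 3, and 103, 80 and 91 without 12 h replicates 1, 2 and 3. The 2 h to 12 h count of 1416 was 844 without 2 h replicate 2, and 928, 732 and 854 without 12 h replicates 1, 2 and 3.

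**Figure D2:**
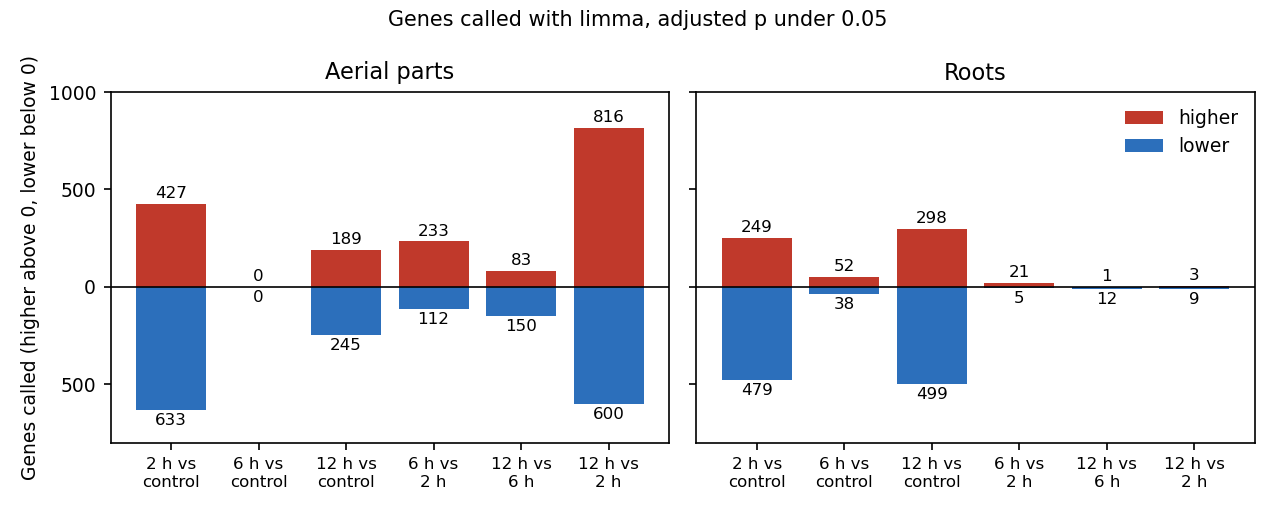
Bars give the number of genes called with limma at an adjusted p under 0.05 in aerial parts and roots, higher above 0 and lower below 0, for each salt time against control and between salt times. From 2 h to 12 h, 1416 genes were called in aerial parts and 12 in roots.

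In roots, 728 of 16138 genes tested changed between controls and 2 h of salt, of which 249 rose and 479 fell. Glyur006124s00045727 rose from 13.6 ± 6.33 TPM (SD, n = 3) to 1598 ± 1703 at 2 h (log2 fold change 6.21, SE 0.74, limma adjusted p = 0.00432) and was still higher at 12 h, at 258 ± 173 (4.04, SE 0.74, limma adjusted p = 0.0173). Glyur000312s00022001 was listed at 0 in all 3 controls and stood at 75.5 ± 27.4 TPM at 2 h (limma adjusted p = 0.0186). Glyur000108s00010429 fell from 472 ± 315 TPM to between 0 and 0.54 (-8.25, SE 1.94, limma adjusted p = 0.0404), and Glyur000005s00001117 stood at 68.3 ± 27.6 TPM in controls and was listed at 0 in all 3 libraries at 2 h (limma adjusted p = 0.0372). Leaving out any 1 of the 6 libraries compared ended both of these calls, with limma adjusted p from 0.0596 to 0.129. So did the lack of a filter on low values (limma adjusted p = 0.0771 and 0.0696) and scaling to the listed total (0.0526 and 0.0501), and the call of Glyur000108s00010429 was also lost with median-of-ratios scaling (0.0537) and with a pseudocount of 5 (0.0581). The call of Glyur000312s00022001 was lost without 2 h replicates 2 or 3 or control replicates 1 or 2, with limma adjusted p of 0.0582, 0.0651, 0.0675 and 0.0537. The median log2 fold change was 2.27 among genes that rose and -1.53 among those that fell. The share of higher genes was 34.2%, against 52.7% with median-of-ratios scaling and 58.8% with scaling to the listed total, which moved the median of all genes from -0.09 to 0.07. Without 2 h replicate 2 there were 40 higher and 83 lower genes. The count was 140 without 2 h replicate 3, and 94 and 176 without control replicates 1 and 2.

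At 6 h, 90 root genes were called, 52 higher and 38 lower, with median log2 fold changes of 2.75 and -1.81. Glyur000122s00010166 rose from 1.13 ± 1.07 TPM (SD, n = 3) to 71.4 ± 28.7 (log2 fold change 5.13, SE 0.72, limma adjusted p = 0.0223). Glyur005977s00044448 stood between 0 and 8.40 TPM in controls and rose to 108.5 ± 16.2 (4.85, SE 0.67, limma adjusted p = 0.0223). Glyur001053s00027289 stood at 94.1 ± 68.8 TPM in controls (limma adjusted p = 0.0083) and Glyur000714s00022867 at 37.8 ± 32.9 (limma adjusted p = 0.0223), and both were listed at 0 in all 9 salt roots. Without 6 h replicate 1 the calls of Glyur000122s00010166, Glyur005977s00044448 and Glyur000714s00022867 were lost, with limma adjusted p of 0.063, 0.0681 and 0.075, and without control replicate 1 the calls of Glyur000122s00010166 and Glyur000714s00022867, both at 0.0921. With only the 6 libraries compared in the fit no root gene was called at 6 h, and the 4 IDs had limma adjusted p of 0.139, 0.212, 0.166 and 0.212 in the order given. Without a filter on low values all but Glyur001053s00027289 were lost (limma adjusted p = 0.0501). Other calls lost were Glyur005977s00044448 with a pseudocount of 0.1 (limma adjusted p = 0.0626) and, with a pseudocount of 5, Glyur000122s00010166 and Glyur000714s00022867 (limma adjusted p = 0.0501 and 0.0634). Of the genes called at 6 h, 32 were also higher and 26 also lower at 2 h, where independent lists would share 0.80 and 1.13. Both lists share their controls, and simulated lists with shared controls and changes placed apart had at most 254 and 442 in common. Relative to independent lists of the same lengths, the observed overlaps were 39.88 and 23.05 times as large, and the simulated ones at most 24.69 and 18.94 times. The 6 h replicate 2 library lay near the controls, at 0.31 on the scale from controls to salt, where left-out controls lay between -0.01 and 0.44 and the other root salt libraries between 0.80 and 1.08. Without it 790 genes were called, 368 higher and 422 lower, and all 90 were among them. The count was 12 and 279 without 6 h replicates 1 and 3, and 15, 36 and 55 without control replicates 1, 2 and 3. The share of higher genes was 57.8%, against 73.4% with median-of-ratios scaling and 83.2% with scaling to the listed total, which moved the median of all genes from -0.06 to 0.14.

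At 12 h, 797 root genes were called, 298 higher and 499 lower, with median log2 fold changes of 2.16 and -1.62. Glyur005977s00044448 reached 260.4 ± 138 TPM (SD, n = 3; log2 fold change 5.99, SE 0.67, limma adjusted p = 0.00331) and Glyur000122s00010166 reached 130.4 ± 89.4 (5.66, SE 0.72, limma adjusted p = 0.00449). Glyur003440s00037452 fell from 2656 ± 1042 TPM in controls to 19.7 ± 7.38 (-7.00, SE 0.64, limma adjusted p = 0.00172). At 2 h it stood at 571 ± 419 in roots, which was not called (-2.51, limma adjusted p = 0.0506). In aerial parts it rose from 31.4 ± 19.8 to 639.5 ± 474 at 2 h (4.17, SE 1.07, limma adjusted p = 0.0431). At 12 h it stood there at 3.29 ± 0.159, below the controls but not called (-2.69, limma adjusted p = 0.186). Glyur000108s00010429 stood between 0 and 0.91 TPM at 12 h (-8.34, SE 1.94, limma adjusted p = 0.0379), a call that ended when any 1 of the 6 libraries compared was left out, with limma adjusted p from 0.0604 to 0.13. It also ended without a filter on low values (limma adjusted p = 0.07) and with a pseudocount of 5 (0.0558). At 6 h the same ID stood at 0.91, 1357.63 and 1.49 TPM, and the high value was that of replicate 2. In aerial parts it stood at 656.42 TPM in 6 h replicate 2 and at no more than 1.84 in any other library. The share of higher genes was 37.4%, against 51.1% with median-of-ratios scaling and 63.7% with scaling to the listed total, which moved the median of all genes from -0.06 to 0.14. The count was 389, 92 and 269 without 12 h replicates 1, 2 and 3, and 206 and 303 without control replicates 1 and 2.

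Between salt times, few root genes moved. From 2 h to 6 h, 21 genes rose and 5 fell, and from 6 h to 12 h, 1 rose and 12 fell. From 2 h to 12 h, the comparison added after the data were seen, 3 genes rose and 9 fell. At an unadjusted p under 0.05 these comparisons had 1540, 1494 and 914 genes, in this order, where 807 would be expected by chance in each. In simulated data of the same size, 54.55%, 53.03% and 50.0% of root genes changed by 2 on the log2 scale were recovered in these comparisons, in the same order. Of those changed by 1, 7.35%, 4.41% and 8.82% were recovered. As in aerial parts, these data did not keep an outlying library within its group. The 2 h and 12 h lists shared 126 higher and 259 lower genes, where independent lists would share 4.60 and 14.8, and 1 gene in each opposite direction. Simulated as in aerial parts, with shared controls and changes placed apart, the lists shared 16.8 higher genes (at most 160) and 23.7 lower genes (at most 163). Relative to independent lists of the same lengths, the observed overlaps were 27.4 and 17.5 times as large, and the simulated ones at most 15.5 and 5.76 times. The covariance of the fold changes was 0.83, where simulated data with no salt effect gave 0.21 (at most 0.40). The 2 h to 6 h count of 26 was 42, 5 and 6 without 2 h replicates 1, 2 and 3, and 5 and 140 without 6 h replicates 1 and 3. The 6 h to 12 h count of 13 was 2 and 204 without 6 h replicates 1 and 3, and 1 and 4 without 12 h replicates 2 and 3. The 2 h to 12 h count of 12 was 24 without 2 h replicate 2 and 21 without 12 h replicate 1, and its share of higher genes was 25.0%, or 35.7% with scaling to the listed total.

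**Figure D3:**
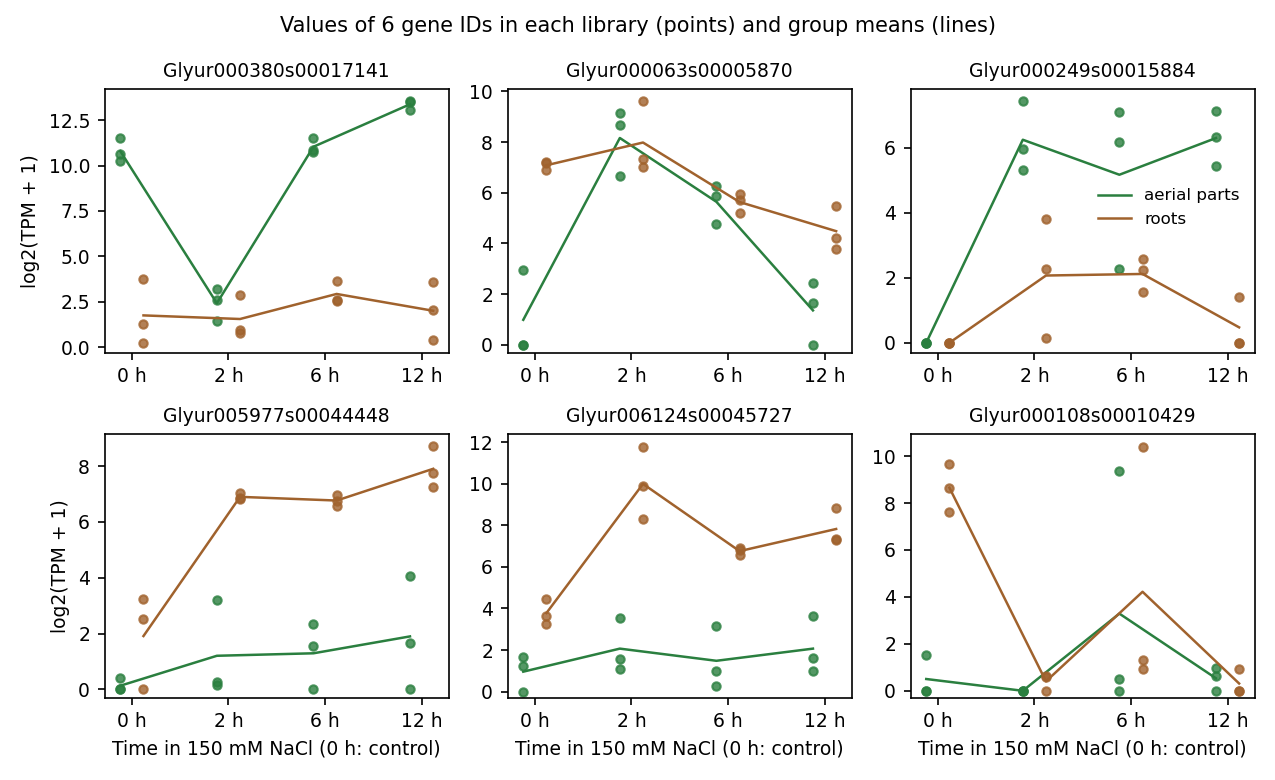
Points are log2(TPM + 1) of 6 gene IDs in each library and lines join the group means, for aerial parts and roots at 0 h (control), 2, 6 and 12 h in 150 mM NaCl. Glyur000380s00017141 drops in aerial parts at 2 h and is highest at 12 h, and Glyur000108s00010429 is high in the 3 root controls and in 6 h replicate 2.

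Many genes moved alike in both organs at 2 h, when 46 rose in both and 110 fell in both. Independent lists over the 14118 genes tested in both would share 5.77 and 19.2 (Fisher's exact test, two-sided, adjusted over 36 tests, p = 2.21e-27 and p = 3.89e-52). Glyur000027s00001583 was among those that fell in both, from 337 ± 174 TPM to 9.18 ± 6.04 (SD, n = 3) in roots (log2 fold change -5.05, limma adjusted p = 0.00845). Opposite calls at 2 h came to 2 genes higher in aerial parts and lower in roots, and 1 gene the other way. At 12 h, 9 genes rose in both and 21 fell in both, where independent lists would share 2.97 and 6.74 (Fisher's exact test, adjusted p = 0.0122 and p = 3.62e-05). The 6 h lists shared none, since limma called 0 aerial genes at that time. Aerial and root libraries were correlated in pairs, so lists with no common effect share more genes than independent ones. In 100 simulated data sets that kept the pairs and placed each organ's changes on genes drawn apart from those of the other, the 2 h lists shared 11.8 higher genes (at most 41) and 20.5 lower genes (at most 66). The simulated lists of lower genes at 2 h were shorter than the real ones, on average 536 and 306 genes against 593 and 458. Relative to independent lists of the same lengths, the observed 2 h overlaps were 7.98 and 5.72 times as large, and the simulated ones at most 4.40 and 2.98 times. The simulated 12 h lists shared 5.74 (at most 21) and 7.72 (at most 32). The observed ratios of 3.03 and 3.12 lay above the simulated means, 2.14 and 1.82, and under the highest simulated ones, 5.73 and 4.98. These overlaps were thus not beyond what paired libraries with changes placed apart gave. Fold changes of the organs correlated across genes at 0.42, 0.36 and 0.38 at 2, 6 and 12 h. Simulated data with the pairs and no salt effect gave 0.27 (at most 0.36), 0.40 (at most 0.63) and 0.28 (at most 0.38). The covariances were 0.37, 0.22 and 0.34, where these data gave 0.09 (at most 0.17), 0.20 (at most 0.63) and 0.09 (at most 0.19), so at 2 h and 12 h the covariance exceeded every simulated one. So did aerial 2 h with root 12 h, at 0.24 (at most 0.14), and aerial 12 h with root 2 h, at 0.23 (at most 0.12). Pairs of times that include 6 h did not. The excess was thus not particular to like times. The simulated data hold no difference of medium or batch, so it cannot be assigned to salt. Genes are not independent replicates here either.

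The salt response differed between the organs for 207 genes at 2 h, of which 99 had the higher response in roots and 108 in aerial parts. The share with the higher response in roots was 47.8%, 53.1% with scaling to the listed total and 41.7% with median-of-ratios scaling, so the larger direction depended on the scaling. Of the 207, 122 were called in aerial parts alone, 52 in roots alone and 3 in opposite directions, and 30 were under 1 TPM in every root library. Glyur006602s00046711 went from 277 ± 210.3 TPM (SD, n = 3) in aerial controls to between 0 and 3.97 at 2 h and 319 ± 106 at 6 h, and stood at no more than 0.41 TPM in any root library (difference in log2 fold change 6.98, SE 0.69, limma adjusted p = 7.25e-05). Glyur000036s00004671 went the other way in aerial parts, from 40.9 ± 8.84 TPM to 217.5 ± 50.6, with no more than 0.39 TPM in roots (-2.26, SE 0.30, limma adjusted p = 0.00107), and its call was lost with a pseudocount of 0.1 (limma adjusted p = 0.321). The salt libraries of the organs share title numbers, and with these numbers as a random block the count was 420, or 697 with the controls also paired by their order. It was 86 without aerial 2 h replicate 2, 130 without aerial control replicate 1 and also without aerial control replicate 3, and 102 without root 2 h replicate 2.

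At 6 h the organs' responses differed for 13 genes, 9 with the higher response in roots, for 26 with title numbers as a random block, and for 56 with the controls also paired by their order. Glyur000270s00013309 was among them, with 21.1 ± 11.2 TPM (SD, n = 3) in root controls and 349 ± 164 in roots at 6 h, against 39.6 ± 35.5 and 10.5 ± 6.65 in aerial parts (difference in log2 fold change 5.66, SE 0.91, limma adjusted p = 0.0205). Its call was lost without root control replicate 1 (limma adjusted p = 0.053). Of the 13 genes, 11 were called in roots alone and 8 were under 1 TPM in every aerial library. The count was 29 without aerial 6 h replicate 1, 7 and 6 without aerial control replicates 1 and 3, 45 and 22 without root 6 h replicates 2 and 3, and 5 without root control replicate 1. Without both 6 h replicate 2 libraries, which lay near the controls in both organs, it was 46. The median difference over all genes was 0.04, and 0.17 with scaling to the listed total.

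At 12 h the responses differed for 193 genes, 114 with the higher response in roots and 79 in aerial parts. Glyur000020s00001835 rose in aerial parts from 20.5 ± 1.35 TPM (SD, n = 3) in controls to 58.2 ± 8.07 and stood at 24 ± 2.52 and 14.7 ± 2.49 in roots (difference in log2 fold change -2.13, SE 0.30, limma adjusted p = 0.00145). Glyur001354s00030737 fell in aerial parts from 105.7 ± 19.1 TPM to 13.7 ± 3.79, after 408 ± 90.4 at 2 h, and stood at no more than 0.29 TPM in roots (3.06, SE 0.34, limma adjusted p = 0.000411). Of the 193, 89 were called in aerial parts alone, 80 in roots alone and 3 in opposite directions, while 35 were under 1 TPM in every root library and 20 in every aerial library. With title numbers as a random block the count was 402, or 781 with the controls also paired by their order. It was 107, 82 and 110 without aerial 12 h replicates 1, 2 and 3, 120, 338 and 119 without aerial control replicates 1, 2 and 3, and 125 and 76 without root 12 h replicates 1 and 2. The median difference over all genes was 0.03, and 0.15 with scaling to the listed total. The change from 2 h to 12 h, compared between organs after the data were seen, differed for 262 genes, of which 253 were called between these times in aerial parts alone and 2 in roots alone, and 68 were under 1 TPM in every root library. That count was 639 with the random block, 523 with the controls also paired, 168 without aerial 2 h replicate 2 and 155 without aerial 12 h replicate 2.

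Roots and aerial parts themselves differed in 5272 of 16718 genes in controls, with 2860 higher in roots and 2412 higher in aerial parts. The share higher in roots was 54.2%, and 46.1% with median-of-ratios scaling, so which direction held more genes depended on the scaling. In salt they differed in 4812 genes at 2 h, 4792 at 6 h and 5328 at 12 h. The shares higher in roots at these times were 55.7%, 57.0% and 56.8%, and 44.6%, 46.7% and 46.3% with median-of-ratios scaling, which moved the median of all genes from 0.20 to 0.01, from 0.20 to 0.02 and from 0.18 to 0.01. In controls it moved the median from 0.11 to 0.00.

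Genes enriched in one organ were followed as groups, a grouping chosen after the data were seen: 674 aerial-enriched and 426 root-enriched genes, each with a mean of at least 10 TPM in its organ and at least 10 times the mean in the other. In roots, root-enriched genes took 9.10 ± 0.0709% of listed TPM in controls (SD, n = 3) and 13.5 ± 2.54% in salt (n = 9), an exact permutation p of 0.00909, two-sided and the smallest possible, or 0.017 adjusted over 15 tests. The share was 15.1 ± 2.34% at 2 h, 11.1 ± 0.666% at 6 h and 14.2 ± 2.48% at 12 h, and without the 10 most abundant of these genes it went from 6.56 ± 0.534% to 9.74 ± 2.31%. This set leans on salt libraries, as set out below, and with the 513 genes root-enriched in controls alone the shares were 12.3 ± 0.256% and 13.1 ± 1.96% (exact permutation p = 0.182, two-sided, with the set drawn anew for each split, or 0.364 adjusted over 2 tests). A higher share in salt was thus not found with that set. At 2 h, 9.62% of root-enriched genes rose in roots against 1.72% of other genes of that level (Fisher's exact test, two-sided, adjusted over 12 tests, p = 9.36e-16), and at 12 h 9.86% against 1.62% (p = 5.24e-17). At 6 h 2.82% rose against 0.217% (Fisher's exact test, adjusted p = 4.38e-08). At 12 h 8.45% of root-enriched genes also fell, against 5.15% of the others (Fisher's exact test, adjusted p = 0.0122), while at 2 h 2.58% fell against 5.32% (p = 0.0179). In aerial parts, 9.35% of aerial-enriched genes fell at 12 h against 2.02% of others (Fisher's exact test, adjusted p = 4.03e-18), and 3.12% rose against 1.82% (p = 0.0361). At 2 h 7.86% of them rose against 4.06% (Fisher's exact test, adjusted p = 6.91e-05) and 10.7% fell against 6.82% (p = 0.001). Their share of listed TPM in aerial parts was 32.9 ± 3.12% in controls and 32.4 ± 3.85% in salt (exact permutation p = 0.809, adjusted 0.809), and with the control-defined set 32.0 ± 3.01% and 30.7 ± 3.72% (exact permutation p = 0.873, adjusted 0.873). Sets defined from means over all libraries favour genes that rose in salt, since 9 of the 12 libraries per organ are salt libraries. With sets from control libraries alone, root-enriched genes still rose more often than others at 2 h (3.70% against 0.942%) and 12 h (2.73% against 0.808%). More of these genes fell than rose at each time, 38 against 19 at 2 h, 8 against 3 at 6 h and 87 of 513 against 14 at 12 h, where 5.62% of others fell (Fisher's exact test, adjusted p = 4.36e-17). Means of controls alone favour genes that fell in salt. With those sets the aerial rise at 12 h did not pass (2.00%, adjusted p = 0.161) and root-enriched genes that fell at 2 h came to 7.41% against 6.19% of others. Fisher's test treats genes as independent, which co-regulated genes are not.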

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

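The differences between organs at 2, 6 and 12 h were planned, while the difference in change from 2 h to 12 h and all tests of explanations and of other splits were chosen after the results were seen. A direct test of the difference between organs found 207 genes at 2 h, 13 at 6 h and 193 at 12 h whose salt response differed between roots and aerial parts, and 262 genes whose change from 2 h to 12 h differed.

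Other splits of the same libraries into salt and control were refitted, with 100 splits for each difference between organs. For the 193 genes at 12 h, 4 of 100 splits gave as many, the real one included, and the highest other gave 937. That share does not count the split with root labels fully reversed, which gave 2634 genes at 12 h. It also ignores the pairing of libraries described below and is not adjusted over the 4 differences tested, so chance is not excluded there. Nor is chance excluded for the 207 genes at 2 h (8 of 100 splits, highest other 822), the 13 at 6 h (26 of 100, highest other 3032) or the 262 (14 of 100, highest other 944). Such large counts point to a structure of the samples, since a split that nearly reverses one organ's labels turns a response shared by the organs into a difference. With the root labels fully reversed the counts were 2888, 635, 2634 and 1315. The split with 3032 genes puts both 6 h replicate 2 libraries with controls in this manner. Title numbers pair the salt libraries, and the 12, 12, 12 and 5 other splits that kept all pairs together, as the real one does, gave at most 4, 32, 1 and 1 genes. Controls of the organs correlate in the order of their titles, and the 5 other splits of each comparison that kept these pairs too gave at most 1, 32, 0 and 1 genes. These splits are too few for a share under 0.05, so chance is not excluded for any of the 4 differences once the pairs are kept.

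For groups of 3 against 3 there are 10 splits, too few for a share under 0.05. In aerial parts the real counts and the highest of the other splits were 1060 and 7 at 2 h, 0 and 118 at 6 h (all 10 splits gave at least 0), 434 and 3 at 12 h, 345 and 14 from 2 h to 6 h, 233 and 2 from 6 h to 12 h, and 1416 and 1 from 2 h to 12 h. In roots they were 728 and 1 at 2 h, 90 and 1200 at 6 h (2 of 10 splits as large), 797 and 1 at 12 h, 26 and 3 from 2 h to 6 h, 13 and 3 from 6 h to 12 h, and 12 and 1 from 2 h to 12 h. The root split with 1200 genes sets 6 h replicates 1 and 3 and control replicate 3 against 6 h replicate 2 and the other controls, which points to a structure of the samples. Between organs they were 5272 and 4 in controls, 4812 and 4 at 2 h, 4792 and 18 at 6 h, and 5328 and 1 at 12 h. The real split parts every title-number pair, and the other splits that part them all gave at most 4, 0 and 0 genes at 2, 6 and 12 h.

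Both 6 h replicate 2 libraries, which share title number 5, lay near the controls, at 0.24 in aerial parts and 0.31 in roots. The tables argue against a library from the control series under a 6 h label, since the root library's listed total of 418244 lies below the lowest root control, 473035. A plant unlike the others in genotype or state is a candidate explanation: 12 IDs were at 5 TPM or more in both libraries and under 1 TPM in the other 22, where the highest of the 143 other pairs of an aerial and a root library had 5. A plant with little response to salt stays open, since the position of 0.31 is the pattern itself. Single IDs of the root library went both ways and do not decide what that plant received. Glyur005977s00044448, chosen with this library included, stood at 92.81 TPM, above the root controls (0 to 8.40). Glyur000108s00010429 stood at 1357.63 TPM, high as in the root controls and unlike the other salt roots. In aerial parts it stood at 656.42 TPM in 6 h replicate 2 and at no more than 1.84 in any other library, controls included. Its high value there was thus unlike the aerial controls. Glyur000005s00001117 stood at 98.01 TPM in the root and 34.34 in the aerial 6 h replicate 2 library, and at 0 in all other salt libraries.

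Controls had higher listed totals and fewer detected IDs than salt libraries in both organs. A library or sequencing batch may be the source, and aerial salt libraries had 1319 more IDs above 0 and under 1 TPM, where deeper sequencing would place them. The salt treatment could also be the source, with root totals at 419183 ± 7344 (SD, n = 3) already at 2 h. Batch and treatment cannot be told apart, because the controls share a title pattern and, per the labels, distilled water in place of the nutrient solution of the salt libraries, a difference in medium that was not tested.

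In aerial parts, 37 genes were called in opposite directions at 2 h and 12 h. No single omission ended all opposite calls, and 8 to 40 genes had them when 1 library was left out. There were 8 without 12 h replicate 2, 13 without 12 h replicate 1 or 3, 11 and 15 without control replicates 3 and 1, and 22 without 2 h replicate 2. Independent lists also share opposite calls, 6.64 and 7.60 with all libraries, and their number was not computed for these fits. Whether a single library is the source of the excess is thus not decided. Time of day cannot be told apart from salt, as no control was taken at these hours. In roots, 25 of the 30 genes tested moved the same way from 2 h to 12 h, while 1 was called. Libraries correlated in pairs make genes chosen for their aerial values tend to move alike in roots, so this count does not decide it. The organs' changes differed for 31 of the 37, which were chosen for their aerial changes, and a response particular to aerial parts also stays open as a hypothesis.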

How the results depend on the processing

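Library quality weights, the test without a trend, the separate treatment of repeated IDs, the omission of both 6 h replicate 2 libraries, control-defined sets, the block with paired controls and all settings of the 12 h to 2 h comparisons were chosen after the data were seen. Apart from omissions of single libraries, 200 of 261 values for the comparisons stayed within 1.5 times the count or on their side of the threshold. A like count need not hold the same genes. With only the groups compared, 425 aerial genes were called at 12 h, of which 268 were among the 434. With median-of-ratios scaling 894 were called at 2 h, and 280 of the 1060 were lost. With 1 library left out, 73 of 144 counts stayed within 1.5 times and 71 did not. Among single IDs, with such omissions included, 526 of 584 values kept their call, none of the 584 changed direction, and 58 lost their call. These IDs were chosen as called and, for comparisons with controls, with no overlap between the groups. For the latter, leaving out a library of the groups compared could not turn the direction. The counts for single IDs thus do not describe genes in general. The cause of the shifts below was not tested, except that fewer libraries give fewer residual degrees of freedom by construction. With library quality weights the counts were 1751 and 2219 in aerial parts at 2 h and 12 h, 862 from 2 h to 6 h, 909 from 6 h to 12 h and 3287 from 2 h to 12 h. In roots they were 2513, 2627 and 3582 at 2, 6 and 12 h, and 53, 73 and 72 between times. The differences between organs came to 725, 104 and 1393 at 2, 6 and 12 h and 997 for the change. With all 24 libraries in the fit the counts were 25 and 874 in aerial parts at 6 h and 12 h, 1548, 439 and 1550 in roots, and 97, 66 and 60 between root times. With only the groups compared they were 408 in aerial parts at 2 h, 82 from 2 h to 6 h and 124 from 6 h to 12 h, and in roots 279 at 2 h, 0 at 6 h, 0 from 2 h to 6 h and 2 from 6 h to 12 h. Without a filter on low values they were 2 and 244 in aerial parts at 6 h and 12 h and 146 from 6 h to 12 h, in roots 396, 10 and 420 at 2, 6 and 12 h and 19 from 2 h to 12 h, and 22 for the difference between organs at 6 h. A pseudocount of 0.1 gave 4 in aerial parts at 6 h, 103, 8 and 121 for the differences between organs and 155 for the change, and a pseudocount of 5 gave 45 in roots at 6 h. The random block of title numbers gave 420, 26 and 402 for the differences between organs and 639 for the change, and with the controls also paired 697, 56, 781 and 523. For the genes that differ between organs, blocks kept the counts within 1.5 times but moved single calls. The fixed block called 5731, 5619 and 6273 genes at 2, 6 and 12 h, lost 161, 205 and 178 of those called without it and added 1080, 1032 and 1123. The random block with paired controls kept all of them and gave 6532 in controls and 5926, 5878 and 6468 in salt. Scaling to the listed total gave 454 in roots at 2 h. The difference at 6 h was 21 genes with repeated IDs kept apart and 46 without both 6 h replicate 2 libraries. At an adjusted p under 0.01 the organs shared 15 calls at 2 h and 4 at 12 h, where 156 and 30 were shared at 0.05. With sets from controls alone, 2.00% of aerial-enriched genes rose at 12 h, and the comparison with other genes turned for root-enriched genes that fell at 2 h (7.41%) and 6 h (1.56%). With those sets the share of root-enriched genes in listed TPM was 0.868 percentage points higher in salt roots than in root controls, against 4.37 with sets from all libraries, and its test did not pass (exact permutation, adjusted p = 0.364, against 0.017).

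Leaving out 1 library at a time gave these lowest and highest counts, with 2 libraries in that group and the spread pooled over groups by limma. In aerial parts they were 461 to 911 at 2 h, 1 to 33 at 6 h, 79 to 852 at 12 h, 132 to 350 from 2 h to 6 h, 80 to 192 from 6 h to 12 h and 732 to 1233 from 2 h to 12 h. In roots they were 94 to 588 at 2 h, 12 to 790 at 6 h, 92 to 548 at 12 h, 5 to 140 from 2 h to 6 h, 1 to 204 from 6 h to 12 h and 8 to 24 from 2 h to 12 h. The differences between organs ranged over 86 to 210 at 2 h, 5 to 45 at 6 h and 76 to 338 at 12 h, and 155 to 266 for the change. Not run were tests of gene lists, since IDs have no names, and the planned count-based tests, filters and normalizations, since the files hold TPM. Depth is unknown from TPM, so what it limits could not be measured.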

Other observations

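The values here and the sets behind them were chosen after the data were seen. Some IDs were listed at 0 on one side of the comparison of controls with salt. In roots, 9 IDs were listed at 0 in all 3 controls and at 1 TPM or more in all 9 salt libraries, and 5 IDs were at 1 TPM or more in all 3 controls and at 0 in all 9 salt libraries. In aerial parts these counts were 2 and 1. The 20 most abundant genes took 15.8 ± 1.88% of listed TPM in aerial controls (SD, n = 3) and 18.2 ± 2.66% in aerial salt libraries (n = 9; exact permutation p = 0.173, two-sided, or 0.236 adjusted over 15 tests). In roots they took 14.6 ± 4.94% in controls and 13.1 ± 3.16% in salt libraries (exact permutation p = 0.582, two-sided, or 0.672 adjusted).

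Glyur000063s00005870, which rose in aerial parts at 2 h, stood there at 2.18 ± 2.21 TPM at 12 h (SD, n = 3), against 2.27 ± 3.94 in controls. In roots it stood at 135 ± 15.3 TPM in controls and at 356 ± 368 at 2 h (log2 fold change 0.90, limma adjusted p = 0.413). At 12 h it fell in roots to 24.6 ± 16.8 (-2.60, SE 0.62, limma adjusted p = 0.0408). At no time was it called in opposite directions in the organs.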
